A study of Homo sapiens with 12 samples.

How the data were processed

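Total RNA of IMR-90 cells was measured on 12 one-colour Affymetrix arrays with 22283 probe sets, 4 samples in each of 3 groups, all after 8 h of culture. The values used are the deposited log2 signals, 1 per probe set and sample, running from 2.33 to 14.11. The log base was inferred from this range, and how the authors summarised, background-corrected and normalized the arrays is not given in the sources used here. The deposited columns had been scaled to each other: their medians differed by 1.18%, so they were analysed without renormalization. Groups and replicate numbers came from the sample labels, and no column was left unused.

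Gene names came from the platform annotation paired with the probe sets. Of the 22283 probe sets, 19071 had 1 gene symbol, 1043 had several and were not named, and 2169 were unnamed here. Of the 19071, 19059 had a gene identifier in the RefSeq table of assembly GRCh38.p14, and 0 symbols needed updating. No coordinates are given.

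Probe sets with a mean log2 signal at or above the 40th percentile over all arrays, 6.216, were tested, which left 13370 probe sets and 8154 named genes. A gene was represented by its probe set with the highest mean, and 2520 genes had more than 1 tested probe set. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided) in 1 fit over all 12 samples, with 9 residual degrees of freedom and 3 contrasts. P-values were adjusted by Benjamini-Hochberg within each contrast, and an adjusted p under 0.05 counted as a call; "rose" and "fell" refer to such calls. Changes are differences of mean log2 signal, with limma's moderated standard error. Figures were drawn with Python and matplotlib.

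Gene lists (30) were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01, adjusted over the 90 tests of 30 lists and 3 contrasts. With an estimated correlation, 2 of the 90 tests passed, both for the hypoxia response list. Named genes were the 10 largest rises and 10 largest falls of each contrast among calls whose groups did not overlap, leaving out probe sets without a single symbol, uncharacterised symbols, XIST and Y-linked genes, and up to 4 members per list with the smallest p-values. The 6 genes given for opposite changes were chosen after their values were seen.

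The comparison of coating and mesh shares the plain dish samples, so unchanged groups were simulated against the same samples in 100 data sets each for changes and for overlaps of calls, and the 4 plain dish samples were also split between the comparisons in 6 ways. Technical measures (3-prime minus 5-prime signal of GAPDH and ACTB, hybridization controls, and ribosomal RNA probes) were compared by two-sided exact permutation tests, for which the smallest possible p is 0.0286. With 15 comparisons that smallest p leaves little room for an adjusted p under 0.05, so the values are given without a verdict. The mesh minus plain dish difference was -0.11 for GAPDH (exact p = 0.0571) and -0.01 for ACTB (exact p = 0.886). The 18S probes ran from 7.18 to 10.24 and differed by -1.11 between mesh and plain dish (exact p = 0.2) and by -0.94 between mesh and coated dish (exact p = 0.0571).

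The tests were tried on simulated data made from the arrays' means and residual spreads, with 200 of 13370 probe sets changed. For mesh against plain dish, 66% of changes of 0.3 on the log2 scale and 100% of changes of 0.5 or more were recovered, with 9 false calls. For mesh against coated dish the shares were 68% and 96% at 0.3 and 0.5, with 19 false calls. For coated against plain dish they were 66% and 100%, with 11 false calls. In the real data far more probe sets passed for the mesh, 66.07% against the plain dish and 63.35% against the coated dish. The Benjamini-Hochberg cutoff depends on that share, so the simulated shares recovered do not carry over to the mesh comparisons.

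Alternatives were quantile normalization, median centring, no filter or a 60th percentile filter on dim probe sets, the replicate number as a block, only the groups compared, eBayes without a trend, leaving out each sample, and for the lists the mean of all probe sets of a gene, an estimated correlation and fry. Leaving out plain dish replicate 1 and coated dish replicate 2 together was added after seeing the data.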

Results

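Gene expression was measured in IMR-90 cells, human lung fibroblasts, on 12 one-colour oligonucleotide arrays. Cells had spent 8 h on one of 3 surfaces: an uncoated tissue culture polystyrene dish (plain dish), a dish coated with collagen and chondroitin sulfate (coated dish), or a three-dimensional mesh of the same material (mesh). Each group had 4 samples. The series title frames the experiment as a biocompatibility test of collagen-glycosaminoglycan material, and the 3 comparisons set mesh against plain dish, mesh against coated dish, and coated dish against plain dish. The labels do not say whether the replicates were separate cultures, so every p-value below measures only the spread between these samples, which can be technical. Median log2 signal per array ran from 6.62 to 6.69, and the number of arrays limits the precision.

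The mesh samples lay far from both dish groups. The first principal component held 80.4% of the variance, with the mesh samples between 33.5 and 37.5 and the 8 dish samples between -22.8 and -11.8. The second component held 4.67% and set plain dish replicate 1 apart, at -18.0. Coated dish replicate 2 had the lowest mean correlation with its own group, 0.473, while mesh samples had 0.886 to 0.900.

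**Figure D1:**
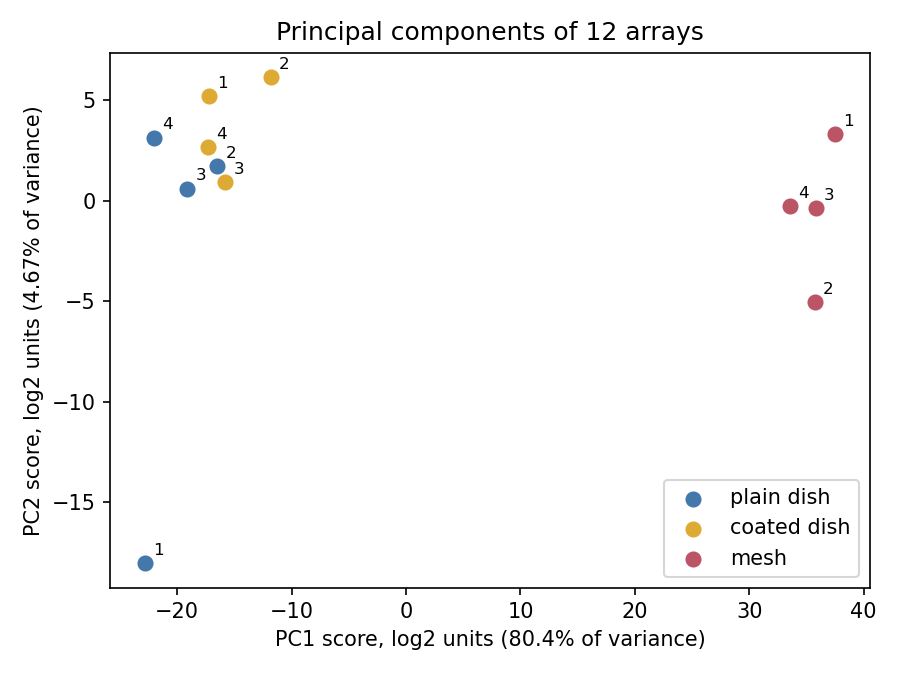
Scores of the 12 arrays on the first (x axis) and second (y axis) principal components of the tested log2 values, with colours for the groups and digits for the replicates. The 4 mesh samples sit between 33.5 and 37.5 on the first component and the 8 dish samples between -22.8 and -11.8.

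Between mesh and plain dish, the largest rises among named genes were in HMOX1, GDF15, DDIT4 and PLIN2 and the largest falls in DKK1, CCN1 and HBEGF. The first of these, HMOX1, is the heme-degrading enzyme induced by oxidative stress, and went from 8.00 ± 0.19 to 11.90 ± 0.25 (mean log2 signal ± SD, n = 4 per group), a 14.9-fold difference. GDF15, a stress-induced cytokine of the TGF-beta family, rose by 3.14 ± 0.10 on the log2 scale (± SE), DDIT4, an inhibitor of mTOR signalling, by 3.10 ± 0.07, and PLIN2, a lipid droplet coat protein, by 2.88 ± 0.08. DKK1, a secreted Wnt inhibitor, was at -4.17 ± 0.10, CCN1, a matricellular protein, at -3.54 ± 0.10, and HBEGF, a ligand of the EGF receptor, at -3.35 ± 0.07. All 7 had limma adjusted p-values at or below 3.31e-14.

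The other genes with the largest rises were CCNG2, an unconventional cyclin (2.51 ± 0.09), the desaturase SCD5 (2.38 ± 0.14), the transcription factors BHLHE40 (2.32 ± 0.11) and MXI1, a MYC antagonist (2.22 ± 0.08), NAMPT, an enzyme of NAD synthesis (2.13 ± 0.12), and TXNIP, a thioredoxin-binding protein (2.12 ± 0.07). The other large falls were in ID1, an inhibitor of differentiation (-2.79 ± 0.14), the potassium channel subunit KCNG1 (-2.77 ± 0.07), the hyaluronan synthase HAS2 (-2.70 ± 0.08), the cytokine IL11 (-2.70 ± 0.14), the neurotrophin BDNF (-2.67 ± 0.10), XYLT1, which starts glycosaminoglycan chains on core proteins (-2.46 ± 0.07), and EFNB2, an ephrin ligand (-2.40 ± 0.12). In each of these genes all 4 mesh samples lay on one side of all 4 plain dish samples.

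**Figure D2:**
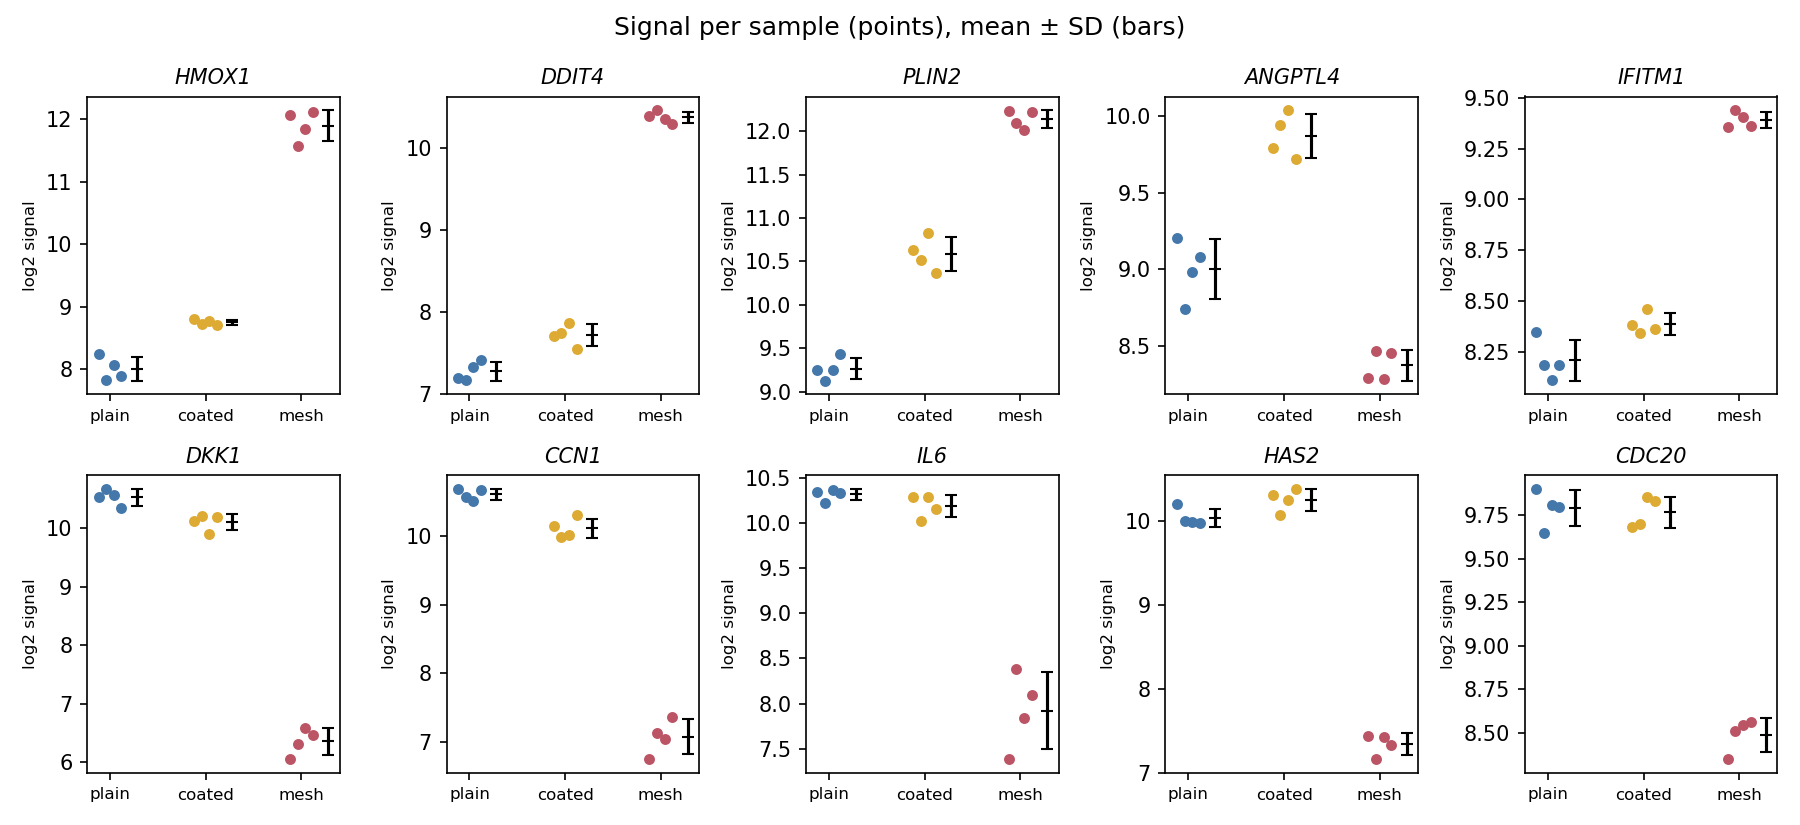
Log2 signal (y axis) of 10 genes in each sample of the plain dish, coated dish and mesh groups (x axis), with points for samples and bars for the mean ± SD, n = 4. HMOX1 averaged 8.00 on the plain dish, 8.75 on the coated dish and 11.90 in the mesh, and DKK1 averaged 10.53, 10.10 and 6.36.

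Hypoxia response genes rose together in the mesh: of 29 measured members 25 rose and 2 fell, the same counts as adjusted over the list alone, with a median change of 0.79. Camera gave adjusted p = 2.58e-13, and adjusted p = 0.0436 with an estimated correlation. Besides DDIT4 and MXI1, its leading members were KDM3A, a histone demethylase, at 1.89 ± 0.07, and ADM, the vasodilator peptide adrenomedullin, at 2.09 ± 0.08. The lowest member, ANGPTL4, went the other way, at -0.63 ± 0.09. Among glycolysis enzymes 11 of 17 rose and 2 fell (11 and 2 adjusted over the list alone), led by ALDOC at 1.47 ± 0.05 and ENO2 at 1.01 ± 0.07. The list test gave adjusted p = 0.000797, and adjusted p = 0.158 with an estimated correlation. Of 22 targets of NRF2, the regulator of antioxidant genes, 14 rose (14 adjusted over the list alone); SQSTM1, an autophagy receptor, rose by 0.88 ± 0.05 and NQO1, a quinone reductase, by 0.67 ± 0.07. For this shift adjusted p = 0.000104 by camera, and adjusted p = 0.156 with an estimated correlation. Of 21 interferon response genes 18 rose (18 adjusted over the list alone), with PSMB9, an immunoproteasome subunit, at 1.53 ± 0.09, TRIM22 at 1.30 ± 0.08 and IFITM1 at 1.18 ± 0.06. By camera adjusted p = 1.55e-07, and adjusted p = 0.156 with an estimated correlation.

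Amino acid response genes were mixed, with 12 of 24 rising and 6 falling (12 and 6 adjusted over the list alone); NUPR1, a stress-induced nuclear protein, rose by 1.06 ± 0.06 while the transporter SLC7A1 fell by 1.18 on the log2 scale. Tested with camera, the list had adjusted p = 0.0309, and adjusted p = 0.465 with an estimated correlation. Among p53 targets 8 of 17 rose and 3 fell (8 and 3 adjusted over the list alone), including the cell cycle inhibitor CDKN1A at 1.16 ± 0.06 and SESN1 at 1.32 ± 0.07. Camera gave adjusted p = 0.0474, adjusted p = 0.0531 with the replicate block, and adjusted p = 0.517 with an estimated correlation. The value was 0.0543 after median centring and, without single samples, 0.0516 (coated dish replicate 2), 0.0509 (coated dish replicate 4), 0.051 (mesh replicate 2), 0.0781 (mesh replicate 3), 0.0693 (plain dish replicate 2) and 0.0562 (plain dish replicate 3), each of which ended the call. Leukocyte markers rose in 7 of 10 measured members (7 adjusted over the list alone), CD3E by 0.54 ± 0.08 from a plain dish mean of 6.89 and MS4A1 by 0.47 ± 0.08 from 6.11. The list test gave adjusted p = 0.0247, and adjusted p = 0.414 with an estimated correlation. The value was 0.0901 after quantile normalization, which ended the call.

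All 32 measured mitosis genes fell in the mesh (32 adjusted over the list alone), with a median of -0.77; ASPM, a spindle pole protein, changed by -1.90 ± 0.10, the kinesin CENPE by -1.45 ± 0.08, and CDC20, an activator of the anaphase-promoting complex, by -1.30 ± 0.07. For this shift adjusted p = 7.43e-11 by camera, and adjusted p = 0.157 with an estimated correlation. After quantile normalization 30 of the 32 fell. Of 33 genes of G1/S and DNA replication 21 fell and 1 rose (21 and 1 adjusted over the list alone), including the flap endonuclease FEN1 at -1.59 ± 0.08. By camera adjusted p = 0.0199, and adjusted p = 0.465 with an estimated correlation. The value was 0.0602 after quantile normalization, which ended the call. Integrin and focal adhesion genes fell in 20 of 27 and rose in 5 (21 and 5 adjusted over the list alone), with FERMT2, an integrin activator, at -1.12 ± 0.07, the focal adhesion kinase PTK2 at -0.90 ± 0.06 and the adaptor PXN at -0.74 ± 0.06. Tested with camera, the list had adjusted p = 0.0222, and adjusted p = 0.339 with an estimated correlation. Heat shock genes fell in 14 of 19 and rose in 3 (14 and 3 adjusted over the list alone), the cochaperone CHORDC1 at -1.72 ± 0.10 and the chaperone HSPH1 at -1.16 ± 0.06. Camera gave adjusted p = 0.0474, adjusted p = 0.0503 with the replicate block, and adjusted p = 0.414 with an estimated correlation. The value was 0.0606 after median centring and, without single samples, 0.0516 (coated dish replicate 2), 0.0547 (mesh replicate 2), 0.0529 (mesh replicate 3), 0.0569 (plain dish replicate 2) and 0.0542 (plain dish replicate 3), each of which ended the call.

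**Figure D3:**
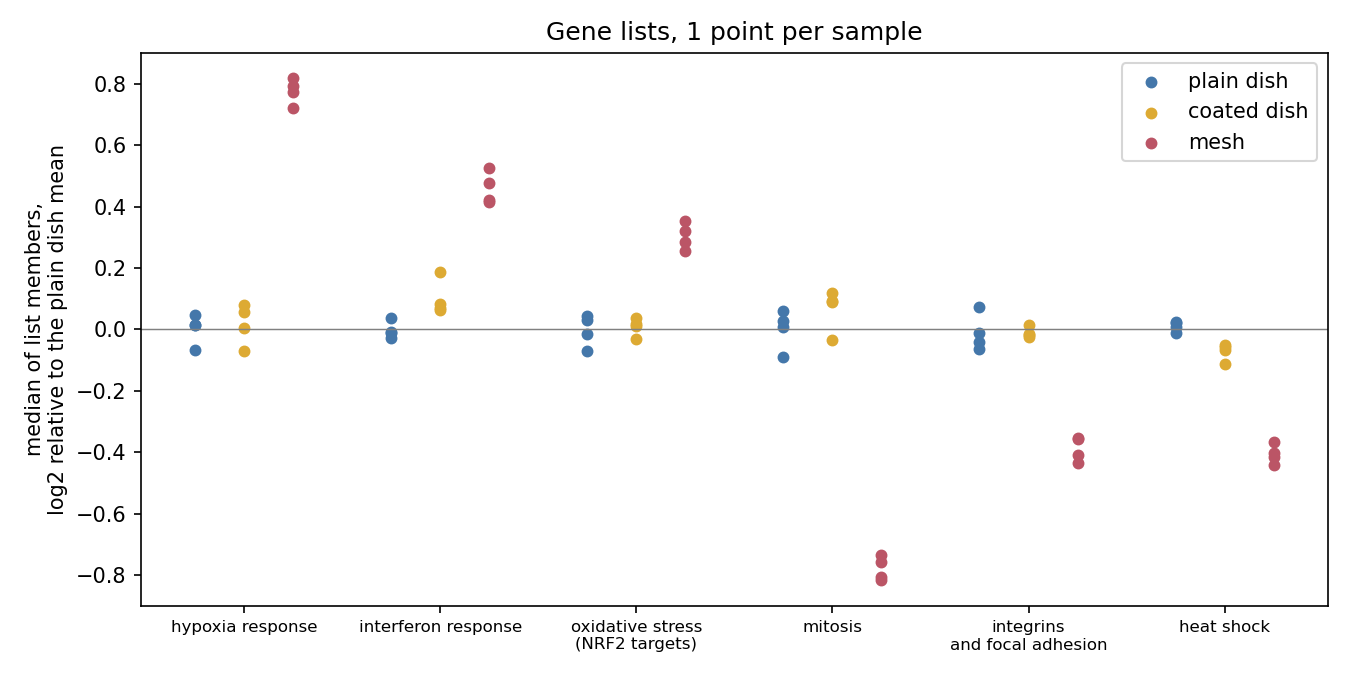
Median log2 signal of the measured members of 6 gene lists (x axis), relative to the mean of the plain dish samples (y axis), with 1 point per sample and colours for the groups. The hypoxia response list, of which 25 of 29 members rose in the mesh, lies highest in the mesh samples, and the mitosis list, of which 32 of 32 members fell, lies lowest.

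The remaining lists did not pass camera's test between mesh and plain dish. TGF-beta response genes fell in 15 of 23 and rose in 4, with ID3 at -2.00 ± 0.13 and the receptor TGFBR2 at -1.05 ± 0.06 (adjusted p = 0.0626; 0.0189 after quantile normalization, 0.0371 without mesh replicate 1 and 0.0456 without plain dish replicate 4). Fibroblast markers had adjusted p = 0.0721, and 0.0394 without plain dish replicate 4. Inflammatory cytokines and NF-kB targets split, with 9 rising and 8 falling of 21; the prostaglandin synthase PTGS2 changed by -1.75 ± 0.11 and the cytokine IL6 by -2.39 ± 0.14. Of 17 YAP and TEAD targets 8 fell and 4 rose, of 30 immediate early genes 13 fell and 11 rose, of 25 angiogenesis factors 13 fell and 7 rose, of 23 matrix proteases and inhibitors 9 rose and 9 fell, and of 28 hyaluronan, proteoglycan and glycosaminoglycan genes 13 fell and 9 rose. Collagen genes rose in 11 of 28 and fell in 7, among them COL3A1 at 0.52 ± 0.04, and matrix glycoproteins rose in 7 of 26 and fell in 11. Of 26 actin and contractile genes 8 rose and 7 fell: the transcription factor SRF changed by -0.95 ± 0.07 and ACTA2, smooth muscle actin, by 0.46 ± 0.05. Of 19 unfolded protein response genes 9 fell and 2 rose, DDIT3 by 1.63 ± 0.07. Counts of rising and falling members were 5 and 6 for cholesterol synthesis, 1 and 2 for metallothioneins, 8 and 7 for oxidative phosphorylation, 9 and 2 for ribosomal proteins, 8 and 3 for fibroblast markers, 5 and 2 for epithelial markers, and 3 and 6 for smooth muscle and pericyte markers; 3 of 5 endothelial markers rose. Adjusted over the list alone, rising and falling members became 10 and 8 for cytokines, 10 and 9 for proteases, 10 and 13 for the hyaluronan list, 6 and 5 for oxidative phosphorylation, 6 and 2 for ribosomal proteins and 2 and 0 for endothelial markers, and stayed the same for the others. The median was above 0 and the mean below 0 for the cytokine, protease and immediate early lists, and the camera direction for cholesterol synthesis was up while its median and mean were below 0. The directions for proteases and ribosomal proteins turned after quantile normalization. Oxidative phosphorylation went to 17 rising and 2 falling after quantile normalization and to 3 and 10 after median centring, and the hyaluronan and immediate early lists went to 13 and 11 and to 14 and 10 after quantile normalization.

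Over all 13370 tested probe sets, 8833 passed between mesh and plain dish (limma, adjusted p under 0.05), 3766 higher and 5067 lower in the mesh, 57.4% of the calls being lower. After quantile normalization 8903 passed, 4798 higher and 4105 lower, so that 46.1% were lower. Changes of at least 2-fold numbered 137 rises and 505 falls, and 199 and 355 after quantile normalization. In 59.5% of the probe sets the groups did not overlap, against 2.86% by chance. KCNG1 had a further tested probe set at 0.06 ± 0.06 that did not pass, and NRP1, a VEGF co-receptor, had 1 probe set at -1.13 ± 0.06 and 1 at 0.25 ± 0.08.

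Against the coated dish, which shares its material, GDF15 rose in the mesh by 3.40 ± 0.10, HMOX1 by 3.15 ± 0.10, DDIT4 by 2.66 ± 0.07, ADM by 2.63 ± 0.08, CEBPD, a transcription factor of the acute phase response, by 2.44 ± 0.09 and CCNG2 by 2.32 ± 0.09. BHLHE40 (2.18 ± 0.11), NAMPT (2.15 ± 0.12), TXNIP (2.13 ± 0.07) and MXI1 (2.07 ± 0.08) completed the 10 largest rises. The largest falls were DKK1 at -3.75 ± 0.10, CCN1 at -3.05 ± 0.10, HAS2 at -2.91 ± 0.08, HBEGF at -2.70 ± 0.07, ID1 at -2.67 ± 0.14 and KCNG1 at -2.65 ± 0.07. IL6 (-2.26 ± 0.14), BDNF (-2.20 ± 0.10), RGS4, a regulator of G protein signalling (-2.18 ± 0.08), and IL11 (-2.16 ± 0.14) followed, and all 20 had limma adjusted p-values at or below 5.25e-10.

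Hypoxia response genes rose in 26 of 29 and fell in 2 (26 and 2 adjusted over the list alone), with ANGPTL4 lowest at -1.50. The list test gave adjusted p = 1.62e-13, and adjusted p = 0.0436 with an estimated correlation. All 32 mitosis genes fell (32 adjusted over the list alone), ASPM at -1.98 ± 0.10 (adjusted p = 2.58e-13; adjusted p = 0.156 with an estimated correlation), and 31 did after quantile normalization. NRF2 targets rose in 14 of 22 (15 adjusted over the list alone). For this shift adjusted p = 0.000104 by camera, and adjusted p = 0.156 with an estimated correlation. Interferon response genes rose in 17 of 21 and fell in 1 (17 and 2 adjusted over the list alone). By camera adjusted p = 5.39e-06, and adjusted p = 0.156 with an estimated correlation. Glycolysis enzymes rose in 12 of 17 and fell in 2 (12 and 2 adjusted over the list alone), HK2 by 0.94 ± 0.08. Tested with camera, the list had adjusted p = 0.000797, and adjusted p = 0.158 with an estimated correlation. Integrin and focal adhesion genes fell in 19 of 27 and rose in 4 (19 and 4 adjusted over the list alone), ITGA2, a collagen-binding integrin subunit, at -1.31 ± 0.09. Camera gave adjusted p = 0.02, and adjusted p = 0.339 with an estimated correlation. Collagen genes rose in 12 of 28 and fell in 3 (12 and 3 adjusted over the list alone), COL3A1 by 0.60 ± 0.04 and PCOLCE, an enhancer of procollagen cleavage, by 0.55 ± 0.06. The list test gave adjusted p = 0.0174, and adjusted p = 0.362 with an estimated correlation.

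The G1/S list fell in 23 of 33 and rose in 1, with the same counts adjusted over the list alone. For this shift adjusted p = 0.00363 by camera, and adjusted p = 0.414 with an estimated correlation. The amino acid response list rose in 15 of 24 and fell in 2 (15 and 2 adjusted over the list alone). By camera adjusted p = 0.00868, and adjusted p = 0.414 with an estimated correlation. The p53 targets rose in 7 of 17 and fell in 3 (7 and 3 adjusted over the list alone), the kinase PLK2 by 1.44 ± 0.09. Tested with camera, the list had adjusted p = 0.0184, and adjusted p = 0.461 with an estimated correlation. Leukocyte markers rose in 7 of 10 and fell in 1 (7 and 1 adjusted over the list alone). Camera gave adjusted p = 0.0474, and adjusted p = 0.461 with an estimated correlation. The value was 0.125 after quantile normalization and, without single samples, 0.0627, 0.0526 and 0.0552 (coated dish replicates 1, 3 and 4), 0.063 and 0.0546 (mesh replicates 1 and 3) and 0.0501 (plain dish replicate 1), each of which ended the call. Ribosomal proteins rose in 11 of 35 and fell in 1 (7 and 1 adjusted over the list alone). The list test gave adjusted p = 0.0346, and adjusted p = 0.638 with an estimated correlation. The value was 0.774 after quantile normalization, 0.108 after median centring and, without single samples, 0.105 (coated dish replicate 2), 0.063 (mesh replicate 2) and 0.0568 (mesh replicate 3), each of which ended the call. In total 8470 probe sets passed, 3651 higher and 4819 lower in the mesh, 56.9% being lower, and after quantile normalization 8517 passed with 46.5% lower.

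The coating alone gave few calls, and their changes were smaller. Between coated and plain dish 1770 of the 13370 probe sets had an unadjusted limma p under 0.05. In 7.88% the groups did not overlap, against 2.86% by chance, so more probe sets may differ than passed. Among the calls, PLIN2 was the only named gene to reach 2-fold. It went from 9.27 ± 0.13 on the plain dish to 10.59 ± 0.19 on the coated dish, a rise of 1.32 ± 0.08. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose by 0.87 ± 0.09, RIN2, a regulator of endocytosis, by 0.87 ± 0.10, HMOX1 by 0.74 ± 0.10, the hormone STC1 by 0.68 ± 0.06 and VGLL4, a TEAD cofactor, by 0.64 ± 0.06. The largest falls were EFNB2 at -0.79 ± 0.12, the growth factor FGF1 at -0.72 ± 0.07, PTGS2 at -0.71 ± 0.11, the oxytocin receptor OXTR at -0.69 ± 0.10, HBEGF at -0.65 ± 0.07 and XYLT1 at -0.65 ± 0.07. All 12 had limma adjusted p-values at or below 0.00143.

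Among the remaining rises were GRAMD2B, a GRAM domain protein (0.54 ± 0.08), the kinase STK38L (0.47 ± 0.07), the osmotic stress factor NFAT5 (0.56 ± 0.12) and the HMG box protein BBX (0.49 ± 0.11), and among the falls the protocadherin PCDH9 (-0.62 ± 0.09), the matricellular protein CCN2 (-0.61 ± 0.13), the chemokine CCL7 (-0.61 ± 0.10) and tuftelin, TUFT1 (-0.58 ± 0.07). The calls of NFAT5 and BBX, at adjusted p = 0.0244 and 0.0275, ended without plain dish replicate 3 (0.0556 and 0.0515), without coated dish replicate 1 (0.0837 and 0.0985), replicate 3 (0.064 and 0.076) or replicate 4 (0.0662 and 0.0622), and with only the 2 groups in the fit (0.0632 for both). The call of CCN2, at 0.0152, ended without coated dish replicate 4 (0.0516).

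Among YAP and TEAD targets, 3 of 17 fell on the coating, CCN2, CCN1 (-0.50 ± 0.10) and IGFBP3 (-0.32 ± 0.05), and 6 did adjusted over the list alone. For this shift adjusted p = 0.000104 by camera, and adjusted p = 0.201 with an estimated correlation. The call of CCN1 ended without coated dish replicate 3, at adjusted p = 0.0538. Angiogenesis factors fell in 7 of 25 and rose in 1 (8 and 2 adjusted over the list alone). By camera adjusted p = 0.004, and adjusted p = 0.326 with an estimated correlation. Matrix glycoproteins fell in 2 of 26 (2 adjusted over the list alone). These were again CCN2 and CCN1, and CCN1 is on the angiogenesis list too, so these list shifts share members and are not separate. Both calls ended without 1 of the coated dish samples, as given above. Tested with camera, the matrix glycoprotein list had adjusted p = 0.00194, and adjusted p = 0.339 with an estimated correlation. Collagen genes fell in 1 of 28 (1 adjusted over the list alone). Camera gave adjusted p = 0.0199, and adjusted p = 0.384 with an estimated correlation. Without single samples it was 0.0508 (plain dish replicate 1), 0.0584 (coated dish replicate 3) and 0.0675 (coated dish replicate 4), each of which ended the call. Heat shock genes fell in 1 of 19 (2 adjusted over the list alone). The list test gave adjusted p = 0.0174, and adjusted p = 0.339 with an estimated correlation. The mitosis and interferon lists shifted up by medians of 0.07 and 0.08 with 0 members of either passing limma's test, over all genes or adjusted over the list alone, and 5 of 32 and 5 of 21 members were higher at an unadjusted p under 0.05 (list adjusted p = 0.000239 and 6.38e-06; adjusted p = 0.414 and adjusted p = 0.156 with an estimated correlation). Integrin and focal adhesion genes had 0 of 27 members passing in limma, with 2 higher and 3 lower at an unadjusted p under 0.05.

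In all, 250 probe sets passed between coated and plain dish, 78 higher and 172 lower, 68.8% being lower; after quantile normalization 215 passed with 57.7% lower. The count dropped to 139 without plain dish replicate 3, and to 132, 128 and 144 without coated dish replicates 1, 3 and 4. Over the 12 left-out samples the numbers higher and lower ran from 34 to 100 and from 86 to 193, and the share lower from 57.2% to 77.8%. Falls also dropped to 102 without coated dish replicate 2 and 111 without plain dish replicate 4.

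PLIN2 and HMOX1 rose on both the coated dish and the mesh against the plain dish, and HBEGF, EFNB2 and XYLT1 fell on both. Of 8154 genes, 30 were higher in both comparisons and 91 lower in both. Independent lists of these sizes would share 14.6 and 45.9, a figure that leaves out the shared plain dish samples, and simulated unchanged groups shared 0, a number that the adjusted threshold holds near 0 without real changes. With the plain dish samples split between the comparisons, 14.3 genes on average were higher in both and 54 lower in both, where independent lists would share 7 and 23.6. The shared plain dish samples push both changes the same way: 65.0% of all genes had changes of the same sign, against 66.7% in simulated unchanged groups. Across genes the log2 changes correlated at 0.424, and unchanged groups simulated against the same 4 plain dish samples gave 0.4998. The covariance of the changes was 0.0228 against a simulated 0.00262. The simulation changed no gene, whereas most tested probe sets passed between mesh and plain dish. Its 66.7% and 0.4998 therefore cannot decide whether the coating and the mesh share a response. With the plain dish samples split between the comparisons, the correlation was 0.317 on average and 0.221 to 0.395 over 6 splits. Simulated unchanged groups split in this way gave -0.0003 on average. Genes are not independent replicates, so these values describe the arrays.

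A set of 22 genes passed in both comparisons in opposite directions, 11 each way, where independent lists would share 53.3. Shared plain dish samples lower such a count, and with them split it was 17.2 on average, against 26.3 for independent lists. The 6 named here were chosen after their values were seen. ANGPTL4 and STC1 rose on the coating and changed by -0.63 ± 0.09 and -0.56 ± 0.06 in the mesh. ADM changed by -0.53 ± 0.08 and HK2 by -0.45 ± 0.08 on the coating, and both rose in the mesh, by 2.09 ± 0.08 and 0.49 ± 0.08. The urokinase gene PLAU was 0.44 ± 0.07 on the coating and -0.48 ± 0.07 in the mesh, and IGFBP3 was -0.32 ± 0.05 and 0.28 ± 0.05. A passing difference between mesh and coated dish was part of how the set was selected, and in these 6 its limma adjusted p-values ran from 1.09e-14 for ADM to 1.93e-08 for HK2. Of the 22 genes, 12 kept both calls whichever sample was left out and 19 kept them after quantile normalization.

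**Figure D4:**
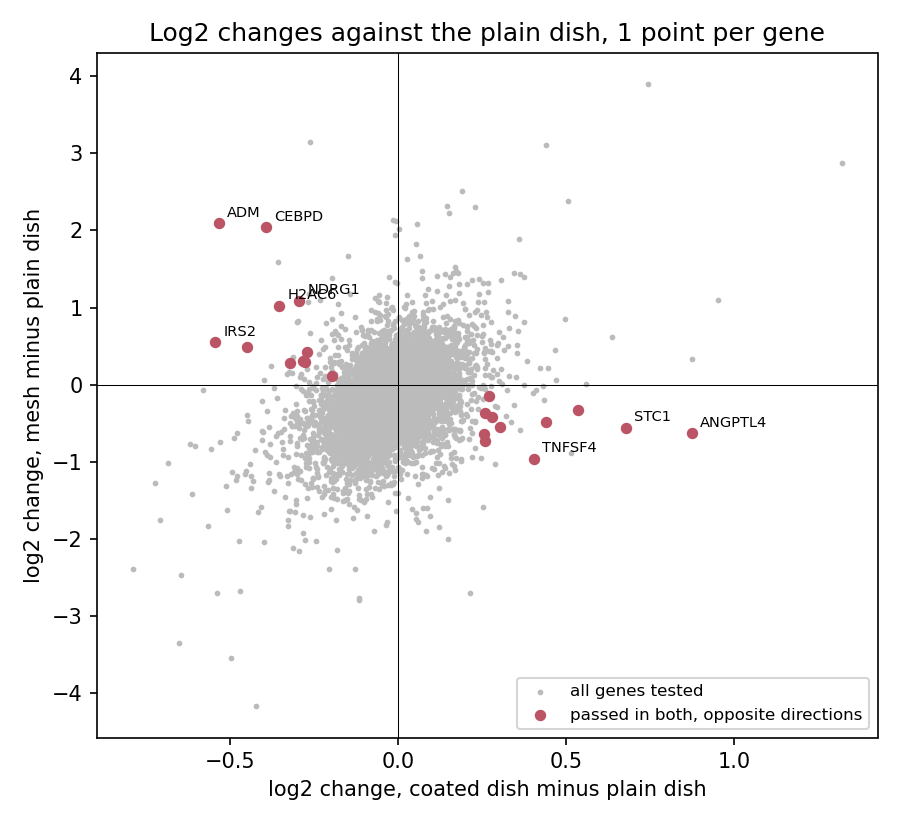
Log2 change between coated dish and plain dish (x axis) against log2 change between mesh and plain dish (y axis), with 1 grey point per tested gene and coloured points for the 22 genes that passed in both comparisons in opposite directions. ADM lies at -0.53 and 2.09, and ANGPTL4 at 0.87 and -0.63.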

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

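The tests of RNA degradation, of dim probe sets and of the shared plain dish samples were chosen after the result was seen. Of 264 gene and group combinations for the 88 tested genes named, 16 had a sample set apart from the other 3 by Dixon's ratio at its 95% limit, where chance alone sets apart about 1 in 20 groups. Plain dish replicate 1 was high for HAS2 (0.901), XYLT1 (0.83) and H2AX (0.837), and replicate 3 was high for FCER1G (0.842). Coated dish replicate 2 was low for NAMPT at 6.36, against 7.06 to 7.07 in the others (0.976), and low for CDKN1B (0.845). In that group replicate 3 was high for ENO2 (0.958), MXI1 (0.839) and SESN1 (0.836) and low for ACTB (0.854), and replicate 4 was low for CCN2 (0.892) and high for HBEGF (0.87). Mesh replicate 2 was high for SCD5 (0.878), replicate 3 was low for FGF1 (0.911) and high for PXN (0.884), and replicate 4 was low for SESN1 (0.876).

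Of the 35 ways to split 8 samples into 4 and 4, only the real one itself passed as many probe sets in each comparison. It passed 8833 against at most 0 in the others for mesh and plain dish, and 8470 against at most 0 for mesh and coated dish. For coated and plain dish it passed 250 against at most 1. Every other split mixes the groups, which adds the real difference to the spread within them. That leaves few calls in any case, so these counts cannot decide on chance. For gene lists, 5 splits passed as many as the real 11 between mesh and plain dish (highest other 12), 3 as many as the real 12 between mesh and coated dish (highest other 14), and 1, the real one, between coated and plain dish (7 against at most 6). Chance was not excluded for the number of passing lists in the mesh comparisons. All 4 and 2 of those other splits put 3 samples of one group with 1 of the other, which keeps part of the real difference, and the 18 splits that put 2 with 2 passed at most 7 and 6 lists.

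Most tested probe sets passed between mesh and plain dish, with more falls than rises. If the different spread of values on the mesh arrays had made the calls, forcing equal distributions would remove most of them, but 8903 passed after quantile normalization, 7602 of the 8833 earlier calls among them in the same direction. The share of falls did follow the distribution, at 46.11% after quantile normalization against 57.4% before. Degraded RNA in the mesh would raise the 3-prime minus 5-prime signal there, and the larger of the GAPDH and ACTB differences was -0.014.

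Between mesh and plain dish 7 of 10 leukocyte markers and 18 of 21 interferon response genes rose, the same counts as adjusted over the list alone (list adjusted p = 0.0247 and 1.55e-07). The lists had adjusted p = 0.414 and adjusted p = 0.156 with an estimated correlation, and the leukocyte list 0.0901 after quantile normalization. If leukocytes were among the mesh cells, genes abundant in them would be higher too, and LYZ, TYROBP, FCER1G, CD14 and PTPRC had a median change of 0.075. That bound was no fair test, because 4 of the 5 lay below the signal filter, at percentiles 2.2 to 27.4 of all probe sets. These values cannot decide on leukocytes, and the cells are described as fibroblasts. In a limma fit without the filter PTPRC was higher by 0.40 ± 0.07 (adjusted p = 6.84e-05), and the other 4 did not pass: LYZ at 0.13 (0.0879), TYROBP at -0.21 (0.0648), CD14 at 0.075 (0.484) and FCER1G, the gene above the filter, at 0.06 (0.57). The leukocyte median lay at percentile 92.19 of 10000 random lists of matched signal, so a general rise of dim probe sets could also account for it, while the interferon median lay at percentile 100. An interferon response of the cells themselves was not tested.

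Probe sets of one gene were called in opposite directions between mesh and plain dish for 182 of 2520 genes with several probe sets, 7.22%. If shared or cross-hybridizing probe sets made these calls, the share would drop among unmarked probe sets, but it was 9.24%. That share covers only 563 genes, a different set from the 2520, so it cannot decide on such probe sets. Among probe sets above the 60th percentile of signal the share was 4.66%, a drop too small to decide on probe sets near background. NRP1, a VEGF co-receptor, had 1 probe set at -1.13 ± 0.06 and 1 at 0.25 ± 0.08, both of which passed. Different transcripts of one gene are a possible biological explanation that the array values cannot test.

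The correlation of coating and mesh changes was at least 0.2207 in each split of the plain dish samples. Simulated unchanged groups split in this way gave -0.0003 on average. In the real data, residuals of samples with the same number in different groups correlated from -0.182 to 0.402, a range that includes 0.2207. Whether the simulation reproduces such correlation was not tested. A deviation common to all plain dish samples would also stay in every split. The splits therefore cannot decide whether chance or the plain dish samples made this correlation.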

How the results depend on the processing

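Counts of probe sets for the mesh comparisons kept within 1.5 times under every setting: 8311 to 8990 for mesh and plain dish and 7667 to 8782 for mesh and coated dish over the 12 left-out samples, 12820 and 12060 without a filter on dim probe sets, and 6231 and 5954 with the filter at the 60th percentile, which test more and fewer probe sets. Coated against plain dish ranged from 128 to 271 as samples were left out, with fewer samples in each fit. Gene lists passing ranged from 26 to 33 of 90 over left-out samples, against 30. An estimated correlation left 2. Against the preset 0.01, the estimates ran from 0.007 for matrix proteases and inhibitors to 0.434 for endothelial markers. They were 0.084 for the hypoxia, 0.114 for the interferon and 0.202 for the mitosis list. How much of the drop they account for was not tested. Fry passed 55. It asks whether a list changed at all, whereas camera sets a list against the other genes, so the counts answer different questions. The correlation of coating and mesh changes went from 0.4241 to 0.3174 with the plain dish samples split between the comparisons. The split leaves fewer samples in each and also removes the shared samples, and the shares of these in the drop were not separated. With quantile normalization the correlation was 0.4048, and the cause was not tested. Without a filter on dim probe sets 44.8% of the mesh calls were lower, against 66.04% above the 60th percentile. Leaving out plain dish replicate 1 and coated dish replicate 2 together, chosen after seeing the data, gave 8801, 8987 and 258 probe sets. Of the 258 between coated and plain dish, 120 were higher and 138 lower, so that 53.49% were lower against 68.8% with all samples. With the replicate block, 8797, 8472 and 229 probe sets and 28 lists passed, and heat shock (0.0503) and p53 targets (0.0531) in the mesh lost their calls; only 4 of 12 samples correlated best with their own number. Of 7460 repeats for 220 genes, 7351 kept their side of the threshold, 84 lost a call, 25 gained 1 and 0 reversed. These genes were chosen for large changes or small p-values, so most were likely to keep their calls. Many of the lost calls were between coated and plain dish, those of NFAT5, BBX, CCN1 and CCN2 among them, so the pooled count does not speak for that comparison. The floors on low values were not run, because the values are already log. Dim signal limits what could be tested: probe sets with a mean under 6.216 were left out.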

Other observations

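The gene families here, and corrected definitions of them, were chosen after the result was seen, as 12 families in 3 comparisons. The division of the histone genes was part of this choice, so the p-values below describe the families and are no independent test. Between mesh and plain dish camera's adjusted p was 0.144 for vacuolar ATPase and lysosome genes and 0.305 for translation initiation factors. It was 0.341 for dual specificity phosphatases, 0.605 for cytosolic tRNA synthetases and 0.0441 for splicing factors, the last 0.363 with an estimated correlation. Histone genes of the clusters (symbols H2AC, H2BC, H3C, H4C and H1-1 to H1-6) rose in 13 of 17 with 0 falling between mesh and plain dish. H2AC6 rose by 1.03 ± 0.07 and H2BC21 by 1.04 ± 0.07. Whether this rise is linked to replication was not tested, and of 33 genes of G1/S and DNA replication 21 fell and 1 rose. The other histone genes split, with H1-10 rising by 1.40 ± 0.10 and H2AX and H2AZ1 at -0.77 ± 0.07 and -0.40 ± 0.07, 2 rising and 4 falling of 7. The cluster genes had camera adjusted p = 5.1e-05 and adjusted p = 0.0295 with an estimated correlation. Of the 24 histone genes of both kinds 15 rose and 4 fell (camera adjusted p = 0.000945; adjusted p = 0.0723 with an estimated correlation). On the coating the cluster genes shifted the other way, with 3 of 17 falling (camera adjusted p = 0.0346; adjusted p = 0.116 with an estimated correlation).

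Ribosome biogenesis factors fell in 42 of 50 and rose in 1, NOP16 at -1.66 ± 0.06 and UTP18 at -1.51 ± 0.07. The family had camera adjusted p = 7.37e-09, and adjusted p = 0.0723 with an estimated correlation. On the coating 4 of 50 fell, with a median change of -0.12 (camera adjusted p = 4.26e-08; adjusted p = 0.0723 with an estimated correlation). With an estimated correlation the family had adjusted p = 0.00309 in all 3 comparisons after quantile normalization, and 0.17 to 0.171 after median centring. Importins and exportins, which carry proteins through nuclear pores, fell in 16 of 20, KPNA2 at -0.94 ± 0.06 (camera adjusted p = 0.000945; adjusted p = 0.106 with an estimated correlation). Proteasome subunits and their assembly chaperones fell in 26 of 33 and rose in 4 (camera adjusted p = 0.00107, and adjusted p = 0.33 with an estimated correlation). The 4 rises were in PSMB9 (1.53), named above among the interferon response genes, PSMB8 (0.73), PSMD10 (0.27) and PSMB10 (0.195). Inhibitors of cyclin-dependent kinases rose in 4 of 5, CDKN1C by 1.82 ± 0.08 and CDKN1B by 1.45 ± 0.11 (camera adjusted p = 0.000857; adjusted p = 0.101 with an estimated correlation).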
